A study of Homo sapiens with 15 samples.

How the data were processed

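Gene expression was measured with Affymetrix oligonucleotide arrays in MCF-7 cells, an established human breast cancer cell line that expresses estrogen receptor alpha (ERα). The 15 arrays fall into 5 groups of 3, by the titles in the labels: parental cells, vehicle, sphingosine-1-phosphate (S1P) at 100 nM, FTY720 at 1 µM and the histone deacetylase (HDAC) inhibitor SAHA (vorinostat) at 1 µM, with 24 h of treatment. Per the labels' protocols, cells were kept in phenol red-free medium with 0.25% glucose and 10% fetal bovine serum, and 500 ng of total RNA per sample was made into biotin-labelled cRNA. The labels number the arrays of a group as replicates and do not say that they came from separate cultures, so p-values measure the spread between these arrays, which may be technical. No array pair held identical values (0 pairs).

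The deposited values are on a log2 scale and were made with RMA (robust multi-array average), per the submitters' processing notes, which give no version. RMA subtracts background, forces the same distribution on every array and summarises the probes of a probe set, so that a change shared by most genes cannot be seen and low levels are compressed. The values carry 2 decimals and cover 22277 probe sets, and array medians lay between 5.96 and 6.04. All value columns matched a sample's label (0 columns were not used). For arrays, depth has no counterpart, and the number of arrays limits the precision: the median standard error (SE) of a log2 difference between 2 groups was 0.079. The fit had 10 residual and 4.75 prior degrees of freedom.

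Gene symbols came from the platform annotation and were updated through Entrez gene IDs with a RefSeq gene table of assembly GRCh38.p14, used for names only. Of the probe sets, 19070 had 1 symbol, 1043 had several and 2164 were not listed or had no symbol. Probe sets without exactly 1 symbol name no gene here. Of the gene IDs, 11954 matched the table and 10 did not, and kept their older symbol. Where a gene had several probe sets (4310 of 11963 genes), the one with the highest mean over all arrays was used, and probe sets of the same gene that disagree are pointed out where the gene is named. No genome build applies to the values, so coordinates are not given. Named genes that no single-symbol probe set measured, such as H1-0 and SPHK2, were not analysed here.

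Differences were tested on the log2 values with limma 3.58.1 in R 4.3.3, with group means for all 15 arrays in 1 fit, empirical Bayes moderation (eBayes) and a Benjamini-Hochberg adjusted p under 0.05 over the 11963 genes. A gene past that threshold is called changed. The comparisons (7) were each treatment against vehicle, vehicle against parental, and the treatments against each other, with a moderated F test over the 5 groups. Fold changes are log2 differences ± SE, and group levels are mean ± SD of 3 arrays. Sets of genes were tested with camera in limma at a preset inter-gene correlation of 0.01, which compares a list with all other genes, with adjustment over the 29 lists within a comparison. A list member is counted as changed over all genes, and separately when adjusted over the list alone. Camera was run again with the correlation estimated from the data, and fry tested whether a list's genes moved, on balance, one way. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

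The design, the gene lists, the rule for naming genes and the first set of alternatives were chosen before the data were examined. The 29 lists held 580 different genes, of which 497 were measured. The lists were ERα target genes, luminal epithelial identity, HDAC inhibitor genes known to rise, HDAC inhibitor genes known to fall, histone deacetylases and acetyltransferases, sphingolipid metabolism, S1P receptors, cholesterol synthesis and uptake, fatty acid synthesis, lysosome, ER stress and amino acid response, mitotic genes, DNA replication genes, p53 target genes, interferon response, histone genes, metallothioneins, immediate early genes, YAP and TEAD target genes, hypoxia and glycolysis, NRF2 target genes, heat shock proteins, ribosomal proteins, oxidative phosphorylation, neuronal genes, BCL2 family and death receptors, basal and mesenchymal breast markers, fibroblast markers and leukocyte markers. Some genes stand in more than 1 list. For each treatment against vehicle, the named genes were the 10 largest rises and 10 largest falls among changed genes whose treated arrays all lay on one side of the vehicle arrays. Where no gene qualified in a direction, the 3 with the smallest p were named and said not to pass. ESR1, TFF1, PGR, GREB1, CDKN1A, H1-0, DHRS2, SPHK1, SPHK2, HDAC1 and HDAC2 were named always (9 of 11 measured), with up to 4 changed members of each list by size. The other comparisons name 5 in each direction by the same rule (3 in each direction where none passed), and the overlap of FTY720 and SAHA names the 10 shared genes with the largest smaller fold.

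The steps were tested on simulated data of 11963 genes with the spread of the real arrays. Per comparison, log2 changes of 0.3, 0.5 and 1 were put into 67, 67 and 66 genes. At a log2 change of 0.3, 38.8% of the changed genes were recovered for FTY720 vs vehicle, 40.3% for S1P vs vehicle and 40.3% for SAHA vs vehicle. At 0.5 these shares were 89.6%, 86.6% and 94.0%, and at 1 they were 100% in each. Over all sizes together there were 6, 7 and 14 false calls. Far fewer genes were changed than SAHA and FTY720 changed in the real data, so the shares hold for that setting. For S1P vs vehicle it was the reverse, with 5 genes called in the real data. With few changed genes the adjusted threshold is harder to reach, so the shares may be too high for S1P. In the list test, the 1 list that was moved was found and 0 others were called. The simulated genes varied independently, so this does not test the preset inter-gene correlation.

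Alternatives were a replicate block, a fit of the compared groups alone, eBayes with trend and robust settings, leaving out the 40% dimmest genes, the mean of all probe sets of a gene, each probe set on its own, quantile normalization again, centring on array medians, array weights, parental or pooled parental and vehicle arrays as the control, other thresholds (adjusted p under 0.01 or 0.10, or at least 1.5-fold), leaving out each array in turn, and RNA integrity covariates. The last are the 3' minus 5' log2 differences of the ACTB and GAPDH control probe sets, in which a larger difference goes with more degraded RNA or shorter cRNA. A covariate from the poly-A spike controls, list member counts without 1 array, S1P genes called against the parental arrays and their values in other comparisons, and the integrity covariates in the list tests were added after seeing the data. Comparisons that share the vehicle arrays also share their chance values, so overlaps are given beside 100 simulations of unchanged groups and beside independent lists.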

Results

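The series asked whether FTY720, a sphingosine analogue whose phosphate resembles S1P, acts as an HDAC inhibitor once phosphorylated and brings back ERα in breast cancer that lacks it. The arrays used here are of MCF-7 cells, which express ERα, treated for 24 h with vehicle, 100 nM S1P, 1 µM FTY720 or 1 µM SAHA, beside parental cells, with 3 arrays in each group. Expression of 11963 genes was compared. Arrays of a group correlated at 0.997 to 0.998 across genes, and the SAHA arrays correlated with those of the other groups at 0.977 to 0.980, where genes are not independent replicates. The 3' minus 5' difference of ACTB, a sign of RNA integrity, was 1.28 ± 0.07 (SD, n = 3) with FTY720, 1.08 ± 0.11 with vehicle, 1.03 ± 0.02 with S1P, 1.16 ± 0.02 with SAHA and 1.18 ± 0.15 in parental cells.

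Vehicle was set against parental cells to give the background of the treatments. No gene passed the threshold (limma, 0 of 11963 at adjusted p under 0.05, 1123 at unadjusted p under 0.05, 598 by chance), and the arrays of the 2 groups did not overlap for 11.2% of genes, where chance gives 10%. The genes with the smallest p did not pass (adjusted p = 0.377). They were DVL3 with a log2 difference of 0.27 ± 0.05, ITGAX with 0.34 ± 0.07 and SPOCK1 with 0.28 ± 0.06 on the higher side, and ANP32A-IT1 with -0.34 ± 0.06, PEX26 with -0.30 ± 0.06 and CENPQ with -0.51 ± 0.11 on the lower side. None of the 29 gene lists passed camera, with adjusted p of 0.124 and above. Median, mean and test differed in sign for metallothioneins, hypoxia and glycolysis, sphingolipid metabolism, fatty acid synthesis and luminal epithelial identity. Without vehicle replicate 1, 99 genes were called (61 higher and 38 lower), DVL3, ANP32A-IT1 and CENPQ among them. That array correlated with the parental arrays at a mean of 0.99813 and with its own group at 0.99714.

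SAHA changed the expression of close to every second gene measured, with 2873 genes higher and 2858 lower than in vehicle (2557 and 3479 with median centred arrays). The largest rises were in AHNAK2, a scaffold protein of the cell periphery, at 4.30 ± 0.11 on the log2 scale (19.7-fold, adjusted p = 3.2e-13), and in GLRX, the redox enzyme glutaredoxin, at 3.74 ± 0.09. They were followed by LOC728392 (3.69 ± 0.17), the phosphatase PPM1E (3.54 ± 0.13), the very long-chain fatty acid elongase ELOVL4 (3.47 ± 0.10), the G protein regulator RGS2 (3.28 ± 0.11), RUNDC3B (3.25 ± 0.15), CRISPLD2 (3.21 ± 0.07), the homeobox factor DLX2 (3.20 ± 0.10) and the actin-bundling protein FSCN1 (3.14 ± 0.09). The largest falls were in the inhibin subunit INHBB (-2.94 ± 0.07), PRDM10 (-2.93 ± 0.16), JADE2 (-2.88 ± 0.09), the transcription factor ZIC1 (-2.83 ± 0.08), the Ras activator RASGRP1 (-2.83 ± 0.10) and the insulin receptor substrate IRS1 (-2.71 ± 0.09). Next came TNFRSF11B, which encodes osteoprotegerin (-2.34 ± 0.13), IRX5 (-2.29 ± 0.09), WIPF1 (-2.29 ± 0.08) and the chemokine receptor ACKR3 (-2.25 ± 0.05). In all, 5731 genes (47.9%) passed limma's test, 498 of them at least 2-fold higher and 313 at least 2-fold lower, and the median size of a called change was 0.45. The arrays of the 2 groups did not overlap for 54.5% of genes, where chance gives 10%. With the mean of all probe sets of a gene, DLX2 stood at 1.65 and PRDM10 at -1.60. AHNAK2, LOC728392, PPM1E, ELOVL4, RGS2, RUNDC3B and DLX2 were among the dimmest genes, which an alternative leaves out. Low levels are compressed, so the sizes of these rises are less certain.

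The gene for ERα, ESR1, was among those that fell with SAHA, from 10.10 ± 0.07 in vehicle to 7.99 ± 0.12 (SD, n = 3), a log2 change of -2.11 ± 0.07 (adjusted p = 1.9e-12). It was lower in 8 of its 9 probe sets, and the change was -0.48 in the mean of all probe sets. The ERα target GREB1 fell by 1.95 ± 0.08. TFF1, another ERα target, differed by -0.10 ± 0.04 (adjusted p = 0.083), past the threshold in 4 alternatives (eBayes with trend and robust settings, without the dimmest genes, median centred arrays and pooled controls) out of a range of 0.0019 to 0.17. PGR, the progesterone receptor gene, differed by 0.03 ± 0.11 (adjusted p = 0.86). PGR was among the dimmest genes, which an alternative leaves out, and low levels are compressed. A small PGR difference therefore says little here, and the same holds for PGR with FTY720 and S1P. Of 29 measured ERα target genes, 13 fell and 6 rose (camera, adjusted p = 0.041, 0.19 with an estimated correlation), among them the corepressor NRIP1 (-2.16), XBP1 (-1.98) and the chemokine CXCL12 (-1.71). Of 18 luminal epithelial identity genes, 8 fell and 3 rose, and the list did not pass camera (adjusted p = 0.092, 3.2e-09 by fry), though FOXA1 (-1.87) and GATA3 (-1.80), transcription factors that act with ERα, fell. Adjusted over the list alone, the counts of these 2 lists were the same.

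SAHA moved the genes known to respond to HDAC inhibitors in the known directions. Of 16 that are known to rise, 14 rose (adjusted p = 8.3e-10), among them the cell cycle inhibitor CDKN1A at 1.03 ± 0.06, DHRS2 at 1.61 ± 0.06, H2BC21 at 1.61 and MT1X at 1.74. Of 11 that are known to fall, 9 fell (adjusted p = 6.3e-05), among them CCND1, which encodes cyclin D1 (-1.61), MYC (-1.09) and CTPS1 (-0.98). Of 15 histone genes 13 rose and 1 fell (adjusted p = 3.7e-08), with H3C2 at 1.91, H1-2 at 1.66 and H2AC6 at 1.57. Of 27 histone deacetylases and acetyltransferases 9 rose and 9 fell (adjusted p = 0.74, 1.7e-08 by fry), and the acetyltransferases CREBBP (-1.55), KAT6B (-1.43) and EP300 (-1.29) were lower and SIRT4 (1.62) higher. CREBBP stood at -0.99 in the mean of all probe sets. HDAC1 rose by 0.13 ± 0.05 (adjusted p = 0.046) and HDAC2 fell by 0.18 ± 0.07 (adjusted p = 0.030), and both calls were lost without any of 4 arrays, at adjusted p of 0.077 to 0.15 without vehicle replicate 1 or 3 or SAHA replicate 2 or 3 for HDAC1, and of 0.062 to 0.11 without vehicle replicate 2 or 3 or SAHA replicate 2 or 3 for HDAC2. Both also failed with parental controls (adjusted p = 0.083 and 0.28), and over all alternatives the ranges were 0.019 to 0.23 and 0.0080 to 0.28. The 1 histone gene that fell was not called when any 1 array was left out. When adjusted over the list alone, the counts of these 4 lists were the same, and the 3 calls held with an estimated correlation (adjusted p = 0.013, 0.013 and 0.042).

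Lipid and lysosomal genes also rose with SAHA. Of 18 genes of cholesterol synthesis and uptake, 14 rose (adjusted p = 8.8e-07), with IDI1 at 1.40, HMGCS1 at 1.39, INSIG1 at 1.32 and SQLE at 1.14. Of 11 fatty acid synthesis genes 7 rose and 1 fell (adjusted p = 0.018, 0.064 with an estimated correlation and 0.052 with the mean of all probe sets), with SREBF1, a master regulator of lipid synthesis, at 1.60, PNPLA3 at 0.85, ACLY at 0.68 and ELOVL5 at 0.57. Of 25 lysosome genes 18 rose and 1 fell (adjusted p = 8.4e-07), with the sialidase NEU1 at 2.36, the cholesterol transporter NPC1 at 2.02, MCOLN1 at 1.08 and GLA at 1.00. Of 23 genes of sphingolipid metabolism 16 rose and 4 fell (adjusted p = 0.011), with the phosphatases PLPP1 at 1.81 and SGPP1 at 1.30, the ceramide synthase CERS2 at -0.83 and SPHK1, the kinase that makes S1P, at -1.12 ± 0.08. Of 19 genes of hypoxia and glycolysis 13 rose (adjusted p = 1.9e-05), with ALDOC at 2.75, EGLN3 at 1.67, NDRG1 at 1.37 and BNIP3L at 1.05. Of 7 metallothioneins 6 rose (adjusted p = 6.5e-05, 0.091 with an estimated correlation), with MT2A at 1.49, MT1H at 1.40 and MT1F at 1.07. No fatty acid gene was called lower (0) without vehicle replicate 2 or 3 or SAHA replicate 1 or 2, and 1 cholesterol gene fell without vehicle replicate 2. Adjusted over the list alone, 19 lysosome genes rose and 5 sphingolipid genes fell, and the other counts were the same. The cholesterol, lysosome, sphingolipid and hypoxia calls held with an estimated correlation (adjusted p = 0.0056, 0.028, 0.042 and 0.013).

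Genes of division and stress moved in both directions with SAHA. Of 30 mitotic genes 19 fell and 5 rose (adjusted p = 0.013, 0.14 with an estimated correlation), with PRC1 at -1.01, CCNA2 at -0.96 and MKI67 at -0.95 but the kinesin CENPE at 0.85. Of 24 genes of ER stress and amino acid response 16 rose and 3 fell (adjusted p = 0.0061, 0.37 with an estimated correlation), with ATF3 at 1.81, HERPUD1 at 1.09 and TRIB3 at -1.37. Of 15 p53 target genes 9 rose and 3 fell (adjusted p = 0.042, 0.14 with an estimated correlation), with the death receptor TNFRSF10B at 2.05, PLK3 at 1.47, PHLDA3 at -1.53 and FAS at -1.07. That call was also lost with the replicate block (0.052), the mean of all probe sets (0.095), parental controls (0.066), the integrity covariates (0.060), the poly-A covariate (0.071), without SAHA replicate 1 (0.052) and without SAHA replicate 3 (0.065). With parental controls, DNA replication genes (adjusted p = 0.031, lower), neuronal genes (0.024, higher) and basal and mesenchymal breast markers (0.031, higher) passed too. In the mean of all probe sets PLK3 stood at 0.78. When adjusted over the list alone, 7 mitotic genes rose, and the other counts were the same.

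The remaining lists did not pass camera with SAHA, that is, they did not stand apart from the other genes measured, though single members changed. By fry, which tests whether a list's genes moved one way without setting them against other genes, basal and mesenchymal (adjusted p = 7.5e-09), NRF2 target (8.9e-06), neuronal (9.3e-05), leukocyte (2.9e-04), immediate early (7.6e-04), heat shock (7.6e-04), interferon (0.0064), DNA replication (0.0091) and oxidative phosphorylation lists (0.010) passed. Of 24 immediate early genes 13 rose and 5 fell (adjusted p = 0.061), with DUSP5 at 1.51, EGR1 at 1.41 and DUSP1 at 1.26. Of 16 genes of the BCL2 family and death receptors 6 rose and 7 fell (adjusted p = 0.78), with the pro-death PMAIP1 at 2.43 and the anti-death BCL2 and CFLAR at -1.96 and -1.49. Of 15 basal and mesenchymal breast markers 6 rose and 1 fell (adjusted p = 0.061), with the transcription factor SNAI2 at 2.07, ANXA1 at 1.38, FN1 at 1.35 and ITGA6 at 0.90. Of 12 YAP and TEAD target genes 5 rose and 5 fell (adjusted p = 1.00), with CCN2 at 2.88, CCN1 at 0.95, THBS1 at -1.06 and AMOTL2 at -0.68, and here the median was -0.21 and the mean 0.17, with a test direction of up. Of 29 DNA replication genes 14 fell and 6 rose (0.13), with CDC6 at 0.90, TK1 at 0.72, MCM2 at -0.69 and TYMS at -0.65, and of 23 interferon response genes 10 fell and 4 rose (0.27), with IRF9 at -1.60, IFI44L at -0.98, OAS1 at -0.84 and PSMB9 at 1.68. Of 12 NRF2 target genes 6 rose and 2 fell (0.13), with HMOX1 at 0.91, GCLC at 0.66, TXNRD1 at 0.52 and FTL at 0.47, and of 11 heat shock proteins 3 rose and 2 fell (0.37), with DNAJB1 at 1.02, BAG3 at -0.79, HSPA4L at 0.66 and DNAJA1 at 0.47. Of 25 neuronal genes 7 rose (0.075), with MAP2 at 1.38, ENO2 at 0.90, TUBB3 at 0.74 and SYN1 at 0.40, and of 23 oxidative phosphorylation genes 6 rose and 2 fell (0.27), with SDHA at 0.33, CYCS at 0.23, UQCRC1 at 0.21 and NDUFV1 at 0.21. Of 12 leukocyte markers 2 rose (0.53), CORO1A by 2.18 and CD14 by 0.35, of 12 fibroblast markers 1 rose (0.76), COL3A1 by 0.40, and none of 4 S1P receptors (0.71) and 16 ribosomal proteins (0.74) were called. Adjusted over the list alone, 8 genes of the BCL2 family fell, 5 oxidative phosphorylation genes rose and 1 fell, 0 fibroblast markers rose, and the other counts were the same. In the mean of all probe sets BCL2 stood at -0.69, CFLAR at -0.68, DUSP1 at 0.81 and THBS1 at -0.59. The COL3A1 call was lost without vehicle replicate 2 or 3 or SAHA replicate 1 or 2 (adjusted p of 0.076 to 0.11), that of UQCRC1 without vehicle replicate 3 or SAHA replicate 2 or 3 (0.068 to 0.12), and that of NDUFV1 without SAHA replicate 2 (0.058). Leaving out 1 array also moved small counts with SAHA. Of the YAP and TEAD target genes 3 rose and 4 fell without vehicle replicate 1 (median -0.10) or SAHA replicate 1, 3 and 3 without SAHA replicate 2, and 4 and 3 without vehicle replicate 3. Oxidative phosphorylation genes ranged from 3 higher (without SAHA replicate 2) to 7 (without vehicle replicate 1), and from 0 to 2 lower. Basal and mesenchymal breast, leukocyte and neuronal lists and the S1P receptors had 0 to 1 lower. COL3A1 was also not called against parental cells (0.53), nor UQCRC1 (0.086) and NDUFV1 (0.059) with median centred arrays.

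**Figure D1:**
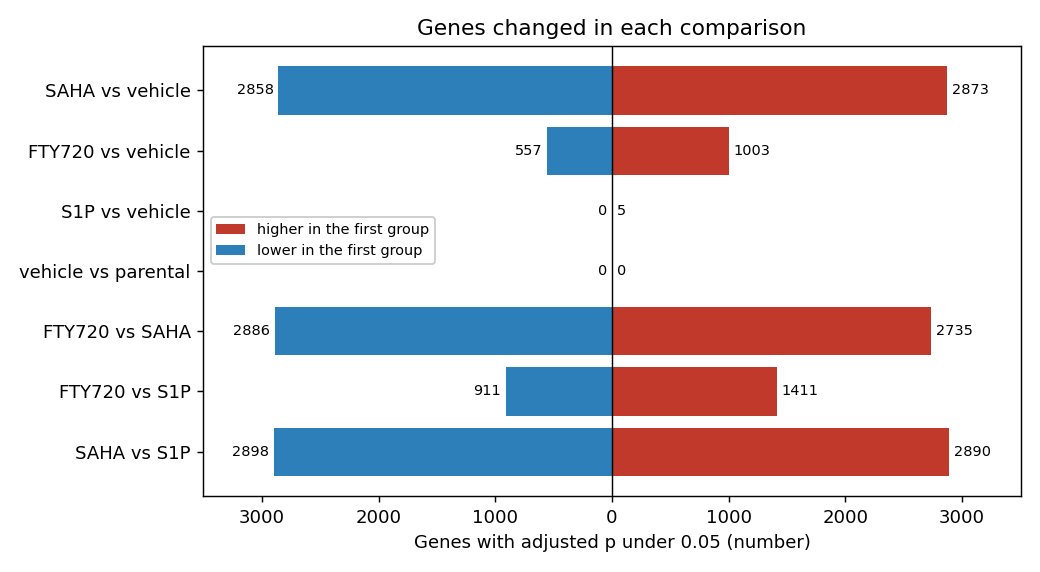
Number of genes with adjusted p under 0.05 in each comparison (horizontal axis), higher in the first-named group to the right and lower to the left. SAHA vs vehicle gave 2873 and 2858 genes, FTY720 vs vehicle 1003 and 557, and S1P vs vehicle 5 and 0.

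FTY720 changed fewer genes than SAHA and by less, with 1003 genes higher and 557 lower than in vehicle. The largest rises were in CCNG2, a cyclin linked to growth arrest, at 1.92 ± 0.08 on the log2 scale (adjusted p = 5.7e-10), in SLC7A11, the cystine transporter, at 1.91 ± 0.18, and in the transcription factor BHLHE40 at 1.89 ± 0.12. LPIN1, an enzyme of lipid synthesis, rose by 1.83 ± 0.07, the stress-induced mTOR inhibitor DDIT4 by 1.81 ± 0.13, the transporter SLCO4C1 by 1.76 ± 0.14, HMGCS1 by 1.71 ± 0.06, INSIG1 by 1.65 ± 0.07, ZNF165 by 1.47 ± 0.11 and the small GTPase GEM by 1.40 ± 0.15. The largest fall was in CCN2, the connective tissue growth factor gene, at -1.02 ± 0.11 (adjusted p = 2.6e-05). It was followed by MALL (-0.61 ± 0.07), the growth factor TGFB2 (-0.61 ± 0.11), CCNE1, which encodes cyclin E1 (-0.61 ± 0.07), SNN (-0.61 ± 0.10), TM4SF1 (-0.60 ± 0.09), the receptor TNFRSF21 (-0.60 ± 0.08), HSPA2 (-0.58 ± 0.11), the splicing factor SRSF7 (-0.58 ± 0.06) and the ascorbate transporter SLC23A2 (-0.58 ± 0.11). In all, 1560 genes (13.0%) passed limma's test, 22 of them at least 2-fold higher and 1 at least 2-fold lower, with a median called size of 0.32 and non-overlapping arrays for 31.6% of genes, where chance gives 10%.

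The FTY720 arrays had the larger 3' minus 5' difference of ACTB (1.28 ± 0.07 against 1.08 ± 0.11 in vehicle, SD, n = 3), while that of GAPDH was 0.34 ± 0.01 against 0.33 ± 0.06. With these integrity measures as covariates, which widened the SE by a median of 1.29 times over all genes, 390 genes were higher and 145 lower (535 in all). TGFB2 then stood at -0.47 ± 0.15 (adjusted p = 0.10), HSPA2 at -0.46 ± 0.14 (0.089) and SLC23A2 at -0.37 ± 0.14 (0.16), and these calls were lost. Without vehicle replicate 2 the count was 808 and without FTY720 replicate 2 it was 787. The share of called genes that were higher was 64.3%, and 51.2% after quantile normalization again (817 higher, 778 lower). In the mean of all probe sets BHLHE40 stood at 1.11, SLCO4C1 at 0.88, TGFB2 at -0.27, SRSF7 at -0.39 and SLC23A2 at -0.23.

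ESR1 did not pass the threshold with FTY720, at 10.29 ± 0.05 against 10.10 ± 0.07 in vehicle (SD, n = 3), a log2 difference of 0.19 ± 0.07 (adjusted p = 0.070). It was higher in 4 of its 9 probe sets, and the difference was 0.01 in the mean of all probe sets. It passed in 5 alternatives (eBayes with trend and robust settings, without the dimmest genes, array weights, pooled controls and the poly-A covariate) out of a range of 0.024 to 0.93. GREB1 differed by 0.20 ± 0.08 (adjusted p = 0.12, past the threshold with trend and robust settings, the compared groups alone and pooled controls, in a range of 0.045 to 0.27), TFF1 by 0.01 ± 0.04 (0.94) and PGR by 0.13 ± 0.11 (0.46). Of 29 ERα target genes 10 rose and 1 fell (camera, adjusted p = 0.0096, 0.15 with an estimated correlation), with NRIP1 at 0.51, SIAH2 at 0.49, the amino acid transporter SLC7A5 at 0.49 and EGR3 at 0.44, and 11 rose and 1 fell when adjusted over the list alone. Of the list's members, EGR3 also stands in the immediate early list, XBP1 in the ER stress list and CTSD in the lysosome list. These lists are thus not independent. Of 18 luminal epithelial identity genes 2 rose (adjusted p = 0.24), ELF3 by 0.35 and FOXA1 by 0.23, with the same count adjusted over the list alone. With the integrity covariates, 5 ERα target genes rose and 1 fell, while the list still passed (adjusted p = 0.0015, with a median of 0.15 against 0.09 without them). The calls of EGR3 (0.44 ± 0.10 before and 0.38 ± 0.11 after, adjusted p = 0.068) and FOXA1 (0.23 ± 0.05 and 0.23 ± 0.07, adjusted p = 0.091) were lost. EGR3 was also not called with parental controls (0.24). Leaving out 1 array, 7 to 9 ERα target genes rose and 1 to 2 fell, and the list still passed (adjusted p up to 0.045), with a median as low as 0.04 without vehicle replicate 1, 0.05 without vehicle replicate 3 and 0.06 without FTY720 replicate 2.

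The HDAC inhibitor lists passed neither camera nor fry with FTY720. Of 16 genes known to rise, 3 rose and 2 fell (camera, adjusted p = 0.81, median -0.03, mean 0.04, direction up): KLF6 at 0.87, CDKN1A at 0.36 ± 0.06 (adjusted p = 0.0012) and H2BC21 at 0.32 were higher, and TUBB3 at -0.31 and DHRS2 at -0.27 ± 0.06 (adjusted p = 0.0063) were lower. Of 11 known to fall, 2 rose and 1 fell (adjusted p = 0.58), MYC by 0.59, ERBB2 by 0.21 and CTPS1 at -0.34. Of 27 histone deacetylases and acetyltransferases 3 rose and 1 fell (camera, adjusted p = 0.30, 0.0026 by fry), SIRT1 at 0.34, KAT6B at 0.31, CREBBP at 0.22 and HDAC1 at -0.19 ± 0.05 (adjusted p = 0.024), while HDAC2 differed by -0.06 ± 0.07 (0.61). Of 15 histone genes 2 rose and 1 fell (adjusted p = 0.32), H2BC21, H1-10 at 0.28 and H2AX at -0.18. When adjusted over the list alone, 3 genes known to fall rose, 2 histone deacetylases and acetyltransferases fell and 4 histone genes rose, and the other counts were the same. The ACTB difference was 1.28 against 1.08, and with the integrity covariates the calls of 9 of these genes were lost. The folds of ERBB2 (0.24 ± 0.07, adjusted p = 0.062), H2BC21 (0.31 ± 0.09, 0.064), KAT6B (0.31 ± 0.08, 0.054), CREBBP (0.20 ± 0.07, 0.14) and H1-10 (0.25 ± 0.10, 0.19) moved by less than their SE without the covariates, and their SE widened. Those of H2AX (-0.14 ± 0.08, 0.33) and HDAC1 (-0.15 ± 0.07, 0.23 in a range of 0.0049 to 0.23) also moved by less, and those of TUBB3 (-0.24 ± 0.07, 0.080) and DHRS2 (-0.19 ± 0.07, 0.15 in a range of 0.00014 to 0.15) by more, toward 0. The HDAC1 call was also lost without vehicle replicate 1 (0.052) or 2 (0.10) or FTY720 replicate 1 (0.086) or 2 (0.076). Leaving out 1 array, 1 to 2 genes known to fall rose and 1 to 2 fell, 2 to 3 histone deacetylases and acetyltransferases rose and 0 to 1 fell, and 1 to 3 histone genes rose and 0 to 1 fell, each vehicle and FTY720 replicate moving at least 1 of these counts. KLF6 stood at 0.50 in the mean of all probe sets, where ERBB2 was not called (0.45), and SIRT1 at 0.18 against parental cells.

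Lipid synthesis genes rose together with FTY720. Of 18 genes of cholesterol synthesis and uptake, 17 rose (adjusted p = 2.1e-30, 4.8e-06 with an estimated correlation, median 0.90), led by HMGCS1 and INSIG1, with MSMO1 at 1.39 ± 0.05 and IDI1 at 1.38 ± 0.09. Of 11 fatty acid synthesis genes 10 rose (adjusted p = 1.8e-18, 3.6e-05 with an estimated correlation, median 0.69), with the citrate lyase ACLY at 0.95, MID1IP1 at 0.84, SREBF1 at 0.83 and the desaturase SCD at 0.82. Of 25 lysosome genes 6 rose (adjusted p = 1.6e-04, 0.091 with an estimated correlation), NEU1 at 0.77, NPC1 at 0.75, NPC2 at 0.50 and SQSTM1 at 0.32 among them. Adjusted over the list alone, the counts of these 3 lists were the same. With the integrity covariates, beside the ACTB difference of 1.28 against 1.08, 13 cholesterol, 10 fatty acid and 4 lysosome genes rose, and all 3 lists still passed (adjusted p = 1.0e-32, 1.6e-19 and 9.7e-06, with medians of 0.89, 0.64 and 0.10). Of 23 genes of sphingolipid metabolism 4 rose (adjusted p = 0.29, 0.038 by fry, and 5 rose and 1 fell adjusted over the list alone), SGPP1 at 0.68, SGMS1 at 0.47, KDSR at 0.27 and CERS6 at 0.25, and SPHK1 differed by -0.21 ± 0.08 (adjusted p = 0.091, in a range of 0.046 to 0.23). Only 2 sphingolipid genes rose without vehicle replicate 1 (with 1 lower) or 2 or FTY720 replicate 1 or 2, and 1 fell without vehicle replicate 3. SPHK1 passed without the dimmest genes and after quantile normalization again. The calls of SGMS1 (0.11), KDSR (0.28) and CERS6 (0.15) were lost with the integrity covariates, at folds of 0.33, 0.23 and 0.24.

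Stress and early response genes rose as well. Of 24 genes of ER stress and amino acid response 16 rose (adjusted p = 9.3e-13, 0.063 with an estimated correlation), with DDIT4, the stress factor DDIT3 at 1.37 ± 0.18, the chaperone DNAJB9 at 1.35 ± 0.11 and HERPUD1 at 1.06 ± 0.10. Of 24 immediate early genes 12 rose and 1 fell (adjusted p = 3.8e-06, 0.20 with an estimated correlation), with ATF3 at 0.96, EGR1 at 0.73 and DUSP4 at 0.71. Of 12 NRF2 target genes 3 rose (adjusted p = 0.0089, 0.063 with an estimated correlation), SLC7A11, ME1 at 0.63 and GCLC at 0.30. Of 30 mitotic genes 10 rose (adjusted p = 8.9e-05, 0.063 with an estimated correlation), with NDC80 at 0.46, TTK at 0.44, CENPE at 0.40 and NUSAP1 at 0.34. Of 7 metallothioneins 3 fell (adjusted p = 0.025, 0.30 with an estimated correlation), MT1F, MT1G and MT1H each at -0.23. When adjusted over the list alone, 19 ER stress genes rose and 1 fell, 14 mitotic and 5 NRF2 target genes rose, 4 metallothioneins fell, and the immediate early counts were the same. With the integrity covariates, beside the ACTB difference of 1.28 against 1.08, 12 ER stress, 7 immediate early, 2 NRF2 target and 2 mitotic genes rose and 0 metallothioneins fell. The first 4 lists still passed with these covariates (adjusted p = 2.0e-15, 1.9e-07, 0.011 and 5.5e-04, with medians of 0.40, 0.22, 0.08 and 0.12). The metallothionein call was lost (adjusted p = 0.28, median -0.06), as it was without vehicle replicate 2 (0.075) or FTY720 replicate 2 (0.066). Leaving out 1 array, 11 to 16 ER stress, 9 to 12 immediate early and 3 to 5 NRF2 target genes rose (5 without vehicle replicate 1), while 0 to 1 immediate early and 0 to 1 NRF2 target genes fell. Without vehicle replicate 1 or 3, 6 mitotic genes rose, and 5 did without vehicle replicate 2 or FTY720 replicate 1 or 2. Metallothioneins that fell numbered 0 without vehicle replicate 2 or FTY720 replicate 1 or 2, and 1 without vehicle replicate 3. ME1 stood at 0.33 in the mean of all probe sets, and NDC80 was not called against parental cells (0.11).

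The remaining lists did not pass camera with FTY720, while hypoxia and glycolysis (adjusted p = 7.9e-04), YAP and TEAD target (0.0024), basal and mesenchymal (0.0036), leukocyte (0.012) and p53 target lists (0.043) passed fry. Of 29 DNA replication genes 4 fell and 1 rose (adjusted p = 0.063), CCNE1, CCNE2 at -0.36, MCM10 at -0.29 and GINS2 at -0.26, and this list passed, lower, with parental controls (0.0029), the integrity covariates (0.0040), the poly-A covariate (0.024), without vehicle replicate 2 (0.031) and without FTY720 replicate 3 (0.0040). Of 19 genes of hypoxia and glycolysis 5 rose and 1 fell (adjusted p = 0.14, and 0.024 with the integrity covariates, median -0.01, mean 0.10, direction up), with the angiogenic factor VEGFA at 0.74, ADM at 0.64, BNIP3L at 0.63 and EGLN3 at -0.36. Of 15 p53 target genes 3 rose and 1 fell (0.30), with CDKN1A, GDF15 at 0.34, CCNG1 at 0.33 and PLK3 at -0.27, and of 16 genes of the BCL2 family and death receptors 3 rose and 2 fell (0.37), with BCL2 at 0.54, XIAP at 0.54, BIRC2 at 0.22 and BAK1 at -0.32. Of 12 YAP and TEAD target genes 1 fell (0.12, and 0.045 with parental controls), CCN2, of 23 interferon response genes 1 rose (0.57), RIGI by 0.28, and of 25 neuronal genes 1 rose and 1 fell (0.35), SYT1 at 0.47 and TUBB3. Of 15 basal and mesenchymal breast markers 1 fell (0.21), VIM at -0.27, of 12 fibroblast markers 2 fell (0.36), ACTA2 at -0.35 and COL1A1 at -0.31, and of 12 leukocyte markers 1 fell (0.21), CORO1A at -0.39. None of 4 S1P receptors (0.39), 11 heat shock proteins (0.45), 16 ribosomal proteins (0.39) and 23 oxidative phosphorylation genes (0.39) were called. Adjusted over the list alone, 5 DNA replication genes and 3 YAP and TEAD target genes fell, 0 interferon response genes rose, and the other counts were the same. Leaving out 1 array, 3 to 6 DNA replication genes fell and 0 rose, 2 to 4 p53 target genes rose and 0 to 1 fell, 2 to 3 genes of the BCL2 family rose and 0 to 2 fell, and 0 to 1 interferon response genes rose or fell. Falls numbered 0 to 1 for hypoxia and glycolysis and for basal and mesenchymal markers, 1 to 2 for YAP and TEAD targets and neuronal genes, and 0 to 2 for fibroblast and leukocyte markers, with each vehicle and FTY720 replicate moving at least 1 of these counts. A probe set of COL1A1 other than the one used was called the other way, and the mean of all probe sets gave 0.03. BCL2 (0.17 on the log2 scale, adjusted p = 0.10) and CCNE2 (0.067) were not called in that mean, where XIAP stood at 0.32.

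Calls of small FTY720 changes among the list members were lost in several settings. With the integrity covariates 34 named genes lost their call, at adjusted p of 0.054 to 0.43. Their folds were 56.0% to 118% of those without the covariates (median 78.9%), and their SE widened by a median of 1.29 times. The fold moved by less than its SE in 19 of them and was as large or larger in 5, which were EGR1 (0.73 and 0.77), ERBB2, FOXA1, GINS2 (-0.26 and -0.27) and PLK3 (-0.27 and -0.32). Among the 34 were EGR1 (0.066), GCLC (0.12), NDC80 (0.080), NUSAP1 (0.17), SYT1, GINS2, PLK3, RIGI, BAK1, BIRC2, VIM, ACTA2, COL1A1, CORO1A, MT1F, MT1G and MT1H. Leaving out a single array ended the call of 21 named genes at adjusted p of 0.050 to 0.18, each without at least 1 of vehicle replicates 1 to 3 and FTY720 replicates 1 to 3. These were ACTA2, BAK1, BIRC2, CERS6, COL1A1, CORO1A, CREBBP, EGLN3, ERBB2, GDF15, GINS2, H1-10, H2AX, HDAC1, KDSR, MT1F, MT1G, MT1H, PLK3, RIGI and VIM. With parental controls 9 named genes lost their call (0.11 to 0.64), SGMS1 (0.11) among them. The compared groups alone ended 10 calls (0.051 to 0.093), the mean of all probe sets 10 (0.056 to 0.75, COL1A1 the highest) and quantile normalization again 6 (0.053 to 0.10).

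**Figure D2:**
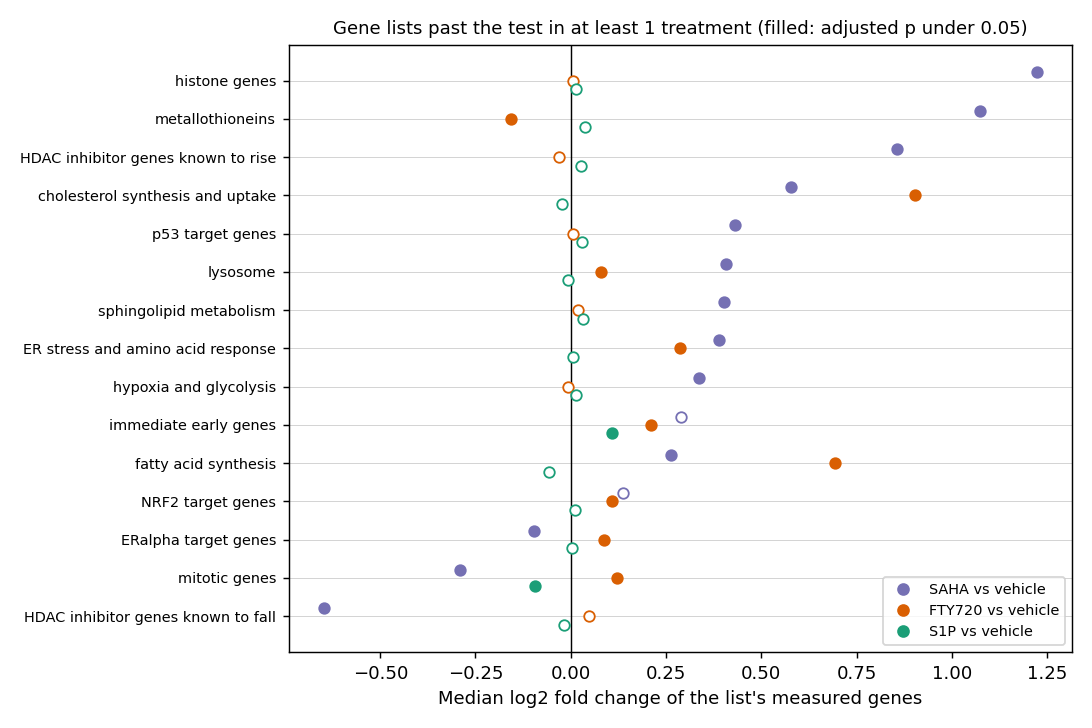
Median log2 fold change against vehicle (horizontal axis) of the measured genes of 15 lists that passed the camera test in at least 1 treatment, with filled points at adjusted p under 0.05. Cholesterol synthesis and uptake genes lie at 0.90 with FTY720, and HDAC inhibitor genes known to rise lie at 0.86 with SAHA and -0.03 with FTY720.

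**Figure D3:**
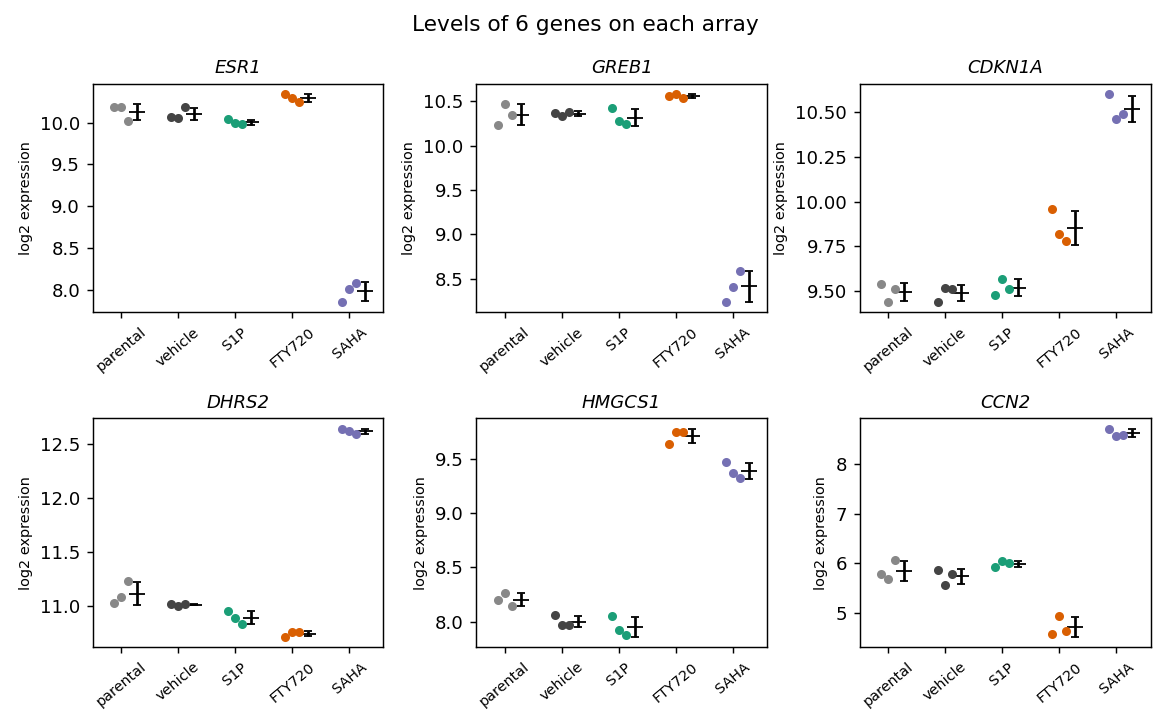
Levels of 6 genes (log2 expression) on each array by group, with the mean and SD of 3 arrays as bars. ESR1 lies at 7.99 with SAHA, 10.29 with FTY720 and 10.10 with vehicle.

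S1P, the natural lipid that phosphorylated FTY720 resembles, raised 5 genes and lowered 0 (limma, 640 genes at unadjusted p under 0.05, 598 by chance). They were MMP1, a collagenase, at 1.03 ± 0.16 (5.15 ± 0.08 against 4.12 ± 0.23 in vehicle, SD, n = 3, adjusted p = 0.032), the receptor TNFRSF21 at 0.97 ± 0.08 (2.2e-05), the membrane protein MALL at 0.86 ± 0.07 (2.2e-05), the actin-associated PALLD at 0.50 ± 0.07 (0.0082) and the monoglyceride lipase MGLL at 0.44 ± 0.07 (0.024). MMP1 was among the dimmest genes, where levels are compressed, so the size of its rise is less certain. The genes with the smallest p on the lower side did not pass: ADRB1 at -0.39 ± 0.09 (0.28), SPOCK1 at -0.29 ± 0.06 (0.27) and TESK2 at -0.25 ± 0.06 (0.30). ESR1 differed by -0.10 ± 0.07 (adjusted p = 0.96), TFF1 by 0.02, GREB1 by -0.05, PGR by 0.22 ± 0.11 (0.93), CDKN1A by 0.03, DHRS2 by -0.12 (0.93), HDAC1 by 0.03 and HDAC2 by 0.00. SPHK1 differed by 0.30 ± 0.08 (adjusted p = 0.34, and 0.046 against parental cells, in a range of 0.046 to 0.997). Arrays of the 2 groups did not overlap for 7.79% of genes, where chance gives 10%.

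The 30 mitotic genes were lower with S1P as a list (camera, adjusted p = 2.4e-08, 0.026 with an estimated correlation, median -0.10), and the 24 immediate early genes were higher (adjusted p = 9.4e-04, 0.50 with an estimated correlation, 0.39 by fry and 0.30 with parental controls, median 0.11). No member of any list was called over all genes, and adjusted over the list alone 1 member each was called higher in sphingolipid metabolism, interferon response, YAP and TEAD target genes and basal and mesenchymal breast markers, and 1 lower in cholesterol synthesis and uptake. The other lists had adjusted p of 0.12 to 0.98. Median, mean and test differed in sign for HDAC inhibitor genes known to fall, fatty acid synthesis, histone genes, oxidative phosphorylation and basal and mesenchymal breast markers. YAP and TEAD target genes passed, higher, with the mean of all probe sets (adjusted p = 0.032), without vehicle replicate 3 (0.036) and without S1P replicate 3 (0.040), as did ERα target genes without S1P replicate 2 (0.049). TNFRSF21 and MALL stayed called in every alternative run (adjusted p up to 0.0049 for both). The count was 2 without vehicle replicate 2, S1P replicate 2 or S1P replicate 3, and 3 without S1P replicate 1. MGLL lost its call without any single vehicle or S1P array (0.057 to 0.14), MMP1 without vehicle replicate 2 or 3 or any S1P replicate (0.074 to 0.22), and PALLD without vehicle replicate 2 or S1P replicate 2 or 3 (0.058 to 0.075). PALLD and MGLL were not called in a fit of the compared groups alone (0.25), nor was MMP1 with the replicate block (0.062). Against parental cells, S1P gave 66 genes higher and 93 lower (159).

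**Figure D4:**
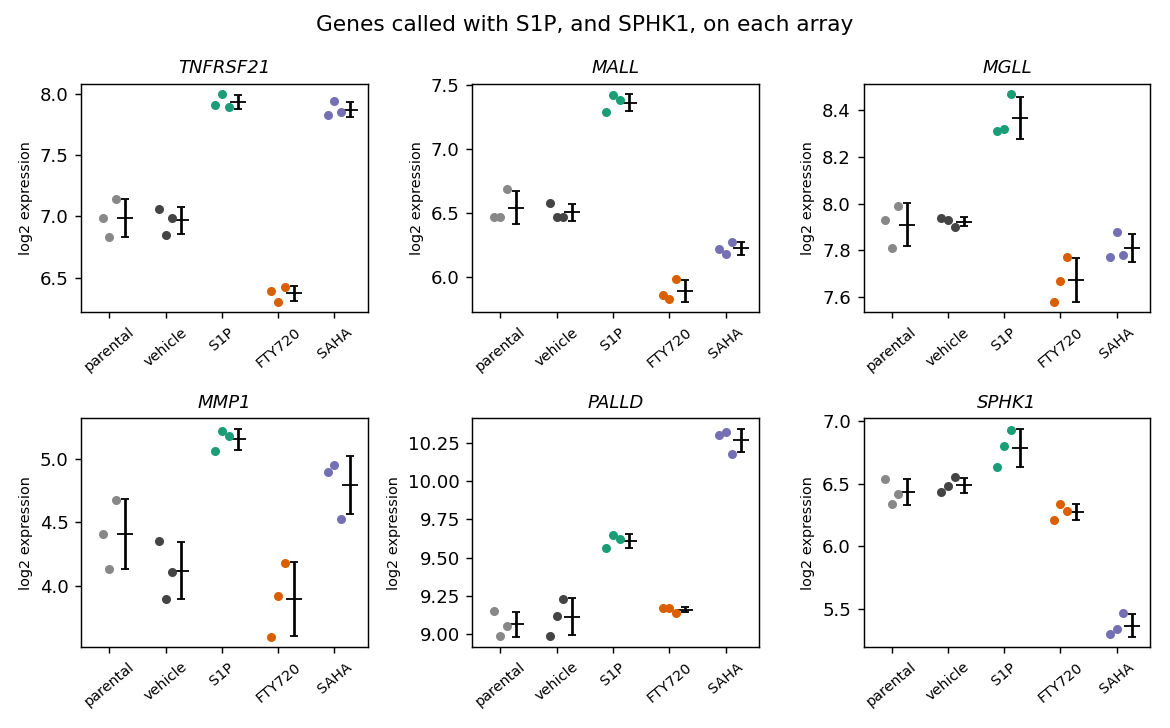
Levels (log2 expression) of the 5 genes called with S1P, and of SPHK1, on each array by group, with the mean and SD of 3 arrays as bars. MMP1 lies at 5.15 with S1P and 4.12 with vehicle.

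FTY720 and S1P were compared directly as a drug and the natural lipid that its phosphate resembles. Their doses differed, at 1 µM and 100 nM, so the values stand side by side and are not matched. With FTY720, 1411 genes were higher and 911 lower than with S1P (2322), and 1163 and 1083 after quantile normalization again. The largest differences were in CCNG2 (2.04), DDIT4 (2.04), LPIN1 (1.95), SLCO4C1 (1.92) and SLC7A11 (1.83) on the higher side, and TNFRSF21 (-1.56), MALL (-1.47), CCN2 (-1.27), MMP1 (-1.25) and TM4SF1 (-1.0) on the lower. Of the genes raised by S1P, MALL (-0.61), TNFRSF21 (-0.60) and MGLL (-0.25 ± 0.07, adjusted p = 0.023) were lower with FTY720 than with vehicle, while PALLD (0.05, adjusted p = 0.69) and MMP1 (-0.22, adjusted p = 0.39) were not called. MGLL differed by -0.69 and PALLD by -0.45 between FTY720 and S1P. No gene changed in the same direction in both (0), where independent lists give 0.42. In opposite directions 3 changed, MALL, TNFRSF21 and MGLL, where independent lists give 0.23. The opposite calls were 2, MALL and TNFRSF21, without any single vehicle or S1P array or FTY720 replicate 1 or 2. With parental cells as the control for S1P, 6 genes were called in the same direction and 40 in opposite ones, where independent lists give 9.86 and 10.9, in a pair of comparisons that share no array. Of the 40, 35 were higher with FTY720 than vehicle and lower with S1P than parental cells. Against parental cells, the 93 genes lower with S1P had medians of -0.21 in vehicle and -0.05 with FTY720. These values share the parental arrays with the choice of genes. The excess may thus follow where the vehicle arrays lay. The log2 folds of FTY720 and S1P correlated at 0.008 across genes, where simulated unchanged groups that share the vehicle arrays gave 0.50, and the covariance was 1.5e-04 against 0.0037 in simulation, a difference of -0.0036. In pairs that share no array, the correlation was -0.07 with parental cells for FTY720 and -0.21 with parental cells for S1P. The covariance there was -0.0013 and -0.0056.

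CDKN1A was higher with FTY720 than with S1P, by 0.33 (95% interval 0.20 to 0.46, adjusted p = 0.0015). In the probe sets used, ESR1 (0.29, 0.15 to 0.43, 0.0073) and GREB1 (0.25, 0.07 to 0.42, 0.048) were higher too, but not in the mean of all probe sets. There ESR1 turned to -0.033 (-0.13 to 0.07, adjusted p = 0.65) and GREB1 stood at 0.13 (-0.07 to 0.34, 0.35). GREB1 was also not called without S1P replicate 2 or 3 or any single FTY720 replicate (0.082 to 0.14), nor with quantile normalization again (0.058) or median centred arrays (0.076). SPHK1 was lower by -0.51 (-0.68 to -0.34, 4.4e-04) and HDAC1 by -0.22 (-0.33 to -0.11, 0.0075). TFF1 (-0.01, -0.10 to 0.08), PGR (-0.08, -0.32 to 0.15), HDAC2 (-0.06, -0.20 to 0.08) and DHRS2 (-0.15, -0.27 to -0.03, adjusted p = 0.079) did not pass, though DHRS2 did in the mean of all probe sets (-0.23, 0.010), with trend and robust settings (0.018), without the dimmest genes (0.039) and with array weights (0.031). Over all alternatives the ranges were 6.5e-04 to 0.65 for ESR1, 0.010 to 0.35 for GREB1 and 0.010 to 0.71 for DHRS2. Among the lists, 17 of 18 cholesterol genes (camera, adjusted p = 1.5e-27) and 10 of 11 fatty acid genes (3.3e-15) were higher with FTY720, as were 15 of 30 mitotic genes (3.4e-09, 0.0077 with an estimated correlation) and 16 of 24 ER stress genes (2.2e-10, 0.11 with an estimated correlation). Immediate early (0.0082, 0.43 with an estimated correlation), lysosome (0.0010, 0.12) and NRF2 target genes (0.045, 0.12) were higher too, and metallothioneins (0.022, 0.35) and YAP and TEAD target genes (0.021, 0.11) lower. The ACTB 3' minus 5' difference was 1.28 with FTY720 and 1.03 with S1P, while that of GAPDH was 0.34 and 0.36. The count was 506 with both as integrity covariates. With these, ESR1 stood at 0.24 (adjusted p = 0.22), GREB1 at 0.30 (0.23) and HDAC1 at -0.18 (0.22 in a range of 8.6e-04 to 0.22), and none of them was called. The count was 1348 without S1P replicate 2 and 1394 without FTY720 replicate 2. SLCO4C1 stood at 0.95 in the mean of all probe sets.

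FTY720 was set against SAHA to ask how far its changes were those of an HDAC inhibitor. Between the drugs, 2735 genes were higher with FTY720 and 2886 lower (5621), and 3017 and 2577 with median centred arrays. PRDM10 (3.61), RASGRP1 (3.04), JADE2 (2.99), ZIC1 (2.95) and INHBB (2.91) led the genes that were higher with FTY720, and AHNAK2 (-4.23), LOC728392 (-3.93), CCN2 (-3.90), GLRX (-3.88) and RGS2 (-3.37) those that were lower. Of 16 HDAC inhibitor genes known to rise, 14 were lower with FTY720 than with SAHA and 1 higher (camera, adjusted p = 8.7e-08, 0.039 with an estimated correlation), and of 11 known to fall, 8 were higher (9.6e-05, 0.034). Histone genes (13 of 15 lower, 1.5e-07, 0.073 with an estimated correlation), hypoxia and glycolysis (12 of 19 lower and 1 higher, 5.8e-04, 0.039), lysosome (17 of 25 lower and 1 higher, 1.2e-04, 0.082) and metallothioneins (6 of 7 lower and 1 higher, 1.2e-04, 0.085) were lower with FTY720. Mitotic genes (20 of 30 higher and 5 lower, 1.2e-04, 0.064 with an estimated correlation), ERα target genes (13 of 29 higher and 5 lower, 0.012, 0.096) and cholesterol genes (10 of 18 higher and 2 lower, 0.037, 0.082) were higher. Sphingolipid (0.049, 0.085 with an estimated correlation), basal and mesenchymal (0.032, 0.082) and neuronal lists (0.049, 0.26) were lower. PRDM10 stood at 1.91 in the mean of all probe sets.

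FTY720 and SAHA shared 699 calls in the same direction, 477 up and 222 down, where independent lists of these sizes give 241 and 133, and 438 genes were called in opposite directions, where independent lists give 373. Simulated unchanged groups that share the vehicle arrays gave 0 shared calls, but they gave at most 1 call in either comparison, so this 0 says nothing of calls that real effects share through the controls. The shared genes with the largest changes were LPIN1 (1.83 with FTY720 and 1.99 with SAHA), CCNG2 (1.92 and 1.40), GEM (1.40 and 2.81), HMGCS1 (1.71 and 1.39), IDI1 (1.38 and 1.40), INSIG1 (1.65 and 1.32), SQLE (1.22 and 1.14), HERPUD1 (1.06 and 1.09), DDIT3 (1.37 and 1.04) and ACSL1 (1.03 and 1.1). CCN2 fell by 1.02 with FTY720 and rose by 2.88 with SAHA. The log2 folds correlated at 0.14 across genes, against 0.50 in simulation, and the covariance was 0.0138 against 0.0038, a difference of 0.0101. In pairs that share no array, the correlation was 0.076 with parental cells for FTY720 and 0.083 with parental cells for SAHA. The covariance there was lower, at 0.0076 and 0.0081. The 3 vehicle arrays are too few to split, so part of the excess may come from the shared controls. With parental cells as the control for FTY720 the counts were 747 same and 557 opposite, where independent lists give 449 and 448. With parental cells for SAHA they were 605 and 454, where independent lists give 364 and 364.5. Calls in both directions thus exceeded independent lists. The shared count was 378 without vehicle replicate 2 and 376 without FTY720 replicate 2. FTY720 arrays also had the larger ACTB 3' minus 5' difference (1.28, against 1.16 with SAHA).

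SAHA and S1P differed in 2890 genes higher and 2898 lower with SAHA (5788), and in 2547 and 3653 with median centred arrays. AHNAK2 (4.27), GLRX (3.86), LOC728392 (3.73), PPM1E (3.65) and RUNDC3B (3.49) were the largest on the higher side, and TNFRSF11B (-3.07), INHBB (-3.02), RASGRP1 (-2.89), JADE2 (-2.86) and PRDM10 (-2.86, and -1.56 in the mean of all probe sets) on the lower. The HDAC inhibitor genes known to rise (14 of 16 higher, camera, adjusted p = 4.1e-09) and known to fall (9 of 11 lower, 8.3e-05) moved as against vehicle. Histone (3.7e-08), cholesterol (4.6e-07), lysosome (1.4e-06) and hypoxia lists (4.8e-05) were higher, and these calls held with an estimated correlation. Metallothioneins (8.3e-05, 0.096 with an estimated correlation), ER stress (0.0078, 0.39), sphingolipid (0.019, 0.055) and fatty acid lists (0.021, 0.071) were higher and ERα target genes (0.019, 0.14) lower. Of the genes raised by S1P, TNFRSF21 (0.91), PALLD (1.15) and MMP1 (0.67) were also higher with SAHA than with vehicle, MALL was lower (-0.28) and MGLL was not called (-0.11, adjusted p = 0.18).

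Across the 5 groups, 6498 of 11963 genes differed by the moderated F test.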

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

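The tests of MALL, MGLL and TNFRSF21 against parental arrays and of the poly-A spikes were chosen only after the result was seen, as were the use of S1P genes called against the parental arrays, their values in other comparisons, and the poly-A covariate. For the 66 S1P genes and for the poly-A spikes, the reading of a test was also changed after its value was seen, as said beside each.

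Of 3151 probe sets without exactly 1 gene symbol, which no comparison above uses, 1034 changed with SAHA, 246 with FTY720 and 2 with S1P against vehicle at adjusted p under 0.05 in limma, and 0 between vehicle and parental cells.

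MALL, MGLL and TNFRSF21, which S1P raised, were lower with FTY720 than with vehicle, and the opposite calls were 2, MALL and TNFRSF21, without any single vehicle or S1P array or FTY720 replicate 1 or 2. Shared vehicle arrays push both folds the same way, which argues against them as the source of opposite calls. The 3 genes were also called lower with FTY720 against the parental arrays (MALL -0.65, MGLL -0.24, TNFRSF21 -0.62). That check uses the same FTY720 arrays that chose the genes, so it adds little. Over the 66 genes called higher with S1P against the parental arrays, the median FTY720 fold against vehicle was 0. Of them 33 were lower, and 70.2% of random lists lay at or below that median. The outcome written beforehand for opposite action was not met. The outcome written beforehand against it, a median of 0 or above, was met as worded, and so was that for shared arrays. The reading was changed after the value was seen: a median of 0 over genes that go both ways decides nothing. It neither brings shared arrays back for the 3 genes nor excludes opposite action on them. With the RNA integrity covariates 2 of the 3 stayed called (MALL at -0.55, TNFRSF21 at -0.56), and MGLL went from -0.25 ± 0.07 to -0.23 ± 0.09 (adjusted p = 0.16), a call that ended because the SE widened, so an integrity difference cannot be told apart for MGLL. An opposite action on these 3 genes may stand as a hypothesis, to which the 66 raised genes gave no support. The 93 genes lower with S1P than in parental cells, looked at afterwards, had a median of 0.14 with FTY720 against vehicle but also 0.10 with SAHA. Against parental cells the FTY720 median was -0.05. The first 2 values share the vehicle arrays, and the last shares the parental arrays that chose the genes. The rise was thus not particular to FTY720 and may depend on where the vehicle arrays lay.

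FTY720 and SAHA shared 699 calls in the same direction, 1.87 times the number that independent lists give. Shared vehicle arrays alone are argued against, since the ratio was still at least 1.66 with parental arrays as one control. Opposite calls also exceeded independent lists in these runs (557 against 448 and 454 against 364.5), so part of that ratio may not be shared direction. Without the lipid and stress lists the ratio was 1.84, with 656 shared calls left. This run kept 11862 of 11963 genes, so too few were removed for the ratio to lose its excess. It shows only that the listed genes do not make up the overlap alone, and says nothing of lipid and stress genes outside the lists. A weaker copy of the whole SAHA response is argued against too, since the genes that SAHA lowered at least 2-fold had a median FTY720 log2 fold of 0.0767, on the other side of 0 (0.06 against parental cells). What stays open is part of the excess from the shared controls, and a partial overlap of the 2 responses, which may be biological but was found and tested on the same arrays.

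Vehicle replicate 1 lay near the parental arrays, and without it 99 genes were called between vehicle and parental cells. On an axis from the parental mean at 0 to the S1P mean at 1, over 159 genes, it lay at 0.25 and vehicle replicates 2 and 3 at 0.61 and 0.47, but FTY720 and SAHA arrays also lay low (0.14 to 0.19 and 0.00 to 0.16), so a parental sample under a vehicle label cannot be told apart from spread within the group. Its mean poly-A spike level was 7.92, inside the parental range of 7.59 to 8.34 and above the other 11 arrays (7.20 to 7.83) by less than the SD within groups of 0.27, a margin set after the value was seen, so a shared labelling day stays open as well. No biological explanation was tested.

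The 6 arrays of a comparison can be split in 10 ways, the real one included, too few for a share under 0.05. The real count and the highest other were 5731 and 0 for SAHA, 1560 and 0 for FTY720 and 5 and 1 for S1P against vehicle, 0 and 3 for vehicle against parental (10 of 10 splits as large), 5621 and 0 for FTY720 against SAHA, 2322 and 6 for FTY720 against S1P, and 5788 and 0 for SAHA against S1P. In each of these except vehicle against parental, 1 of 10 splits, the real one, was as large. With parental and vehicle arrays pooled as the control, a random division of the arrays was argued against for SAHA (6003 genes, highest other 1, 1 of 84 splits as large) and FTY720 (2193, highest other 9, 1 of 84). The arrays of a group may come from a single culture, so these splits cannot exclude chance differences between cultures. For S1P the real 15 genes were reached in 4 of 84 splits, a share under 0.05, but the other 3 gave 44, 25 and 24 genes. Those with 44 and 24 grouped 2 parental replicates with vehicle replicate 1, which points to a structure of the samples, so these splits do not settle chance for S1P. For the F test, 1 of 100 partitions gave as many as the real 6498, and the highest other, 4248, kept the 3 SAHA arrays together.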

How the results depend on the processing

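The alternatives with the poly-A covariate, the S1P genes called against parental cells, the list tests with integrity covariates, and the list member counts with integrity covariates or without 1 array were chosen after seeing the data. Named genes and lists called in the main test kept their direction in the alternatives that gave 1 value per gene, with 2 exceptions. In the mean of all probe sets, COL1A1 with FTY720 turned from -0.31 to 0.029 (a probe set it holds was called the other way). There ESR1 between FTY720 and S1P turned from 0.29 to -0.033. With each probe set on its own, direction was not part of this comparison. Of the other values of named genes, 3171 kept their side of the threshold, 104 lost it and 19 gained it, and 1602, 111 and 3 when 1 array was left out. For lists these were 559, 23 and 27, and 513, 4 and 5. Causes were not tested, except where the construction shows them (fewer arrays, more probe sets, another threshold).

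For SAHA vs vehicle, each probe set on its own gave 9485 calls and a 1.5-fold minimum 2056, and leaving out 1 array 5251 to 5508. For FTY720 vs vehicle, array weights gave 2577, integrity covariates 535, adjusted p under 0.01 634 and under 0.10 2388, a 1.5-fold minimum 132, and leaving out 1 array 787 to 1342. For S1P vs vehicle, the compared groups alone gave 3, trend and robust settings 13, the mean of all probe sets 8, each probe set 14, parental controls 159, pooled controls 15, adjusted p under 0.01 3 and under 0.10 10, a 1.5-fold minimum 3, and leaving out 1 array 2 to 5. For vehicle vs parental, leaving out 1 array gave 0 to 99. FTY720 vs SAHA gave 9295 with each probe set, 2133 at 1.5-fold and 5161 to 5360 without 1 array. FTY720 vs S1P gave 506 with integrity covariates, 1102 at adjusted p under 0.01, 207 at 1.5-fold and 1348 to 2416 without 1 array. SAHA vs S1P gave 9602 with each probe set, 2101 at 1.5-fold and 5248 to 5814 without 1 array, and the F test 10894 with each probe set and 5991 to 6748 without 1 array. The overlap of FTY720 and SAHA was 1076 at adjusted p under 0.10, 61 at 1.5-fold and 376 to 648 without 1 array, and that of FTY720 and S1P 6 with parental controls for S1P and 0 to 0 without 1 array. Lists called numbered 13 for SAHA (7 with an estimated correlation, 24 by fry, 12 to 13 without 1 array), 9 for FTY720 (2, 16, 8 to 10) and 2 for S1P (1, 1, 1 with parental controls, 2 to 3).

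Arrays with the same number were not paired: over 30 same-number pairs the correlation of deviations was -0.16 to 0.21 (median 0.01), 4 were over 0.1, and 6 of 15 arrays correlated best with their own number. With the replicate block the counts were 5719, 1502 and 6 for SAHA, FTY720 and S1P vs vehicle, 0 for vehicle vs parental, 5584 for FTY720 vs SAHA, 2173 for FTY720 vs S1P, 5729 for SAHA vs S1P and 6386 for the F test. Overlaps were 688 and 0, and lists called 12, 9 and 2. The block ended the calls of MMP1 (adjusted p = 0.062, in a range of 0.00081 to 0.22), KDSR, MT1G, GREB1 (FTY720 against S1P) and the p53 list with SAHA (0.052). The deposited values hold no separate measure of signal near background, so levels of dim genes are limited by compression.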

Other observations

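The S1P genes called against parental cells, and their values in other comparisons, were chosen for a test only after the result was seen.

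The genes lower with S1P than in parental cells (93) had a median FTY720 fold against vehicle of 0.14, as high as in 0.01% of 10000 random lists matched on expression, which is the smallest share they can give. The random lists do not keep the way these genes may vary together between arrays, so the share does not test an FTY720 effect. In vehicle against parental cells, 0.01% of random lists had a median as low as that of these genes. Of these genes 35 were called higher and 3 lower with FTY720 against vehicle, a pair of comparisons that share no array. The rise over vehicle was not particular to FTY720: with SAHA against vehicle the median was 0.10, with 41 called higher and 25 lower. Vehicle itself had a median of -0.21 against parental cells for these genes (0 called), FTY720 -0.05 (9 called higher, 14 lower) and SAHA -0.11 (28 higher, 40 lower), in comparisons that share the parental arrays with the choice of the genes. Of the 66 genes higher with S1P than in parental cells, 3 were called higher and 5 lower with FTY720 against vehicle, and 23 higher and 6 lower against parental cells. In this set, 58 of 66 (87.9%) were lower with FTY720 than with S1P, a comparison that shares the S1P arrays with the choice of the genes.

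Of 498 genes raised at least 2-fold by SAHA, 118 were called higher and 32 lower with FTY720, with a median fold of 0.08 against vehicle and 0.03 against parental cells. Of 313 genes lowered at least 2-fold by SAHA, 13 were called lower and 67 higher with FTY720.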
